A study of Mus musculus with 60 samples.

How the data were processed

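Bacterial communities were profiled by sequencing amplicons of the V3 to V4 stretch of the 16S rRNA gene, a gene whose sequence tells bacterial taxa apart. The samples were stool collected after 1 week and at day 28, and colon tissue, lung tissue and oral swabs collected at day 28, from male mice. Per the labels, DNA of stool and oral swabs was taken with a kit for soil-like material and DNA of lung and colon with a kit for blood and tissue, so that kit and site are partly confounded. Reads were paired and 300 bases long.

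The deposited table holds counts: the number of reads of each sequence feature in each library, as whole numbers with no normalization. Per the file headers it was built from a biom file. The submitters' processing notes name cutadapt, Bowtie2 and the mouse genome build GRCm39, with no version, role or order. The denoiser, the classifier and the reference database are not given in the sources used here. A deposited taxonomy table gives each feature a lineage and a classifier confidence, a fraction with a lowest value of 0.332, a median of 0.994 and a highest value of 1. Of 8574 features, 7955 have a line in that table and 619 have none.

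Features without a taxonomy line, chloroplast, mitochondrial and eukaryote features and features unassigned at domain level were left out of the main analysis. This kept 7922 prokaryote features, which hold 99.3% of all counts, under 566 genus labels. A feature without a genus name was placed under its lowest named rank as "unclassified". Of the prokaryote features, 73.8% were detected in 1 library each. Library totals ran from 10543 to 1083575 counts. PCR counts without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 over a whole group was read as allowing up to 3 counts, and folds against such a group are lower bounds at that floor. They take the pooled share of the other group as it is. They therefore cover neither its counting error nor the spread between its libraries. Shares of single libraries carry 95% Wilson intervals.

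Libraries were placed in 10 groups of 6 by their labels for site, time and exposure. The design text gives 12 mice, 6 per arm, but no label ties a library to an animal across sites or times, so nothing was paired. All tests, taxon lists and the rule for named taxa were fixed before the data were examined, except where the text says otherwise.

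Exposed and unexposed libraries were compared at each site and time on counts summed by genus. The test was the quasi-likelihood F test of edgeR 4.0.16 with TMM normalization, the Benjamini-Hochberg correction and a threshold of 0.05. Genera needed a total of 10 counts and a count above 0 in 3 libraries of the fit. The change of stool from week 1 to day 28 in each arm, and the difference of the exposure effect between the times, came from 1 fit of all 24 stool libraries. Adjusted p-values of genera are from edgeR unless another tool is named. Community difference was the PERMANOVA R2 of Bray-Curtis distances between feature shares, the part of the squared distances that lies between the arms. Its p was exact, over all 462 splits of 12 libraries. Shannon index (natural log) and richness (expected number of features) were computed at the lowest prokaryote total of each comparison and compared by exact two-sided permutation tests over 924 arrangements. These families were each adjusted over 5 comparisons. Lung counts were also summed over features detected in at least 3 day 28 stool and colon libraries, and over features detected in at least 3 oral swab libraries.

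The 22 taxon lists were butyrate producers, acetate and propionate producing Bacteroidota, lactic acid bacteria and bifidobacteria, mucus-associated genera, sulfate and sulfite reducers, enterobacteria, rodent oral and airway genera, skin and bedding genera, common reagent contaminants, genera with described PET hydrolases, the families Lachnospiraceae, Muribaculaceae, Erysipelotrichaceae, and Oscillospiraceae with Ruminococcaceae, a pool of gut anaerobe families, and the phyla Firmicutes, Bacteroidota, Proteobacteria, Actinobacteriota, Verrucomicrobiota, Desulfobacterota and Campylobacterota. Each list was tested in 5 comparisons by an exact two-sided permutation test of log2((list counts + 0.5)/(library total + 1)), adjusted over all 110 tests. Members share genera across lists.

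Named taxa are the 10 most abundant genera of each exposure comparison, up to 10 highest and 10 lowest genera past the threshold, and list members past the threshold. For the time contrasts and the interaction the rule takes up to 6 and 6 genera past the threshold.

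Alternatives covered normalization (TMMwsp, library totals), tool (DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log ratios, an exact permutation test per genus), low count filters, robust spread, non-bacterial features, taxonomic level, distance measure, rarefaction, singletons, reference sets, list statistics, reagent genera, 4 libraries with later numbers, and each library left out in turn. The later numbers belong to day 28 stool control library 6 and PET library 6, and to lung control libraries 5 and 6. Whether these were a separate run is not given in the sources used here. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

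The genus test was tested on simulated data with the real means and library sizes, in 5 rounds. Over these rounds each comparison had 50 changes of 4-fold and 50 of 16-fold, made in the same simulated tables. With a dispersion of 0.2 it recovered 82 to 94% of 4-fold changes and 100% of 16-fold changes. False calls were counted once over both sizes of change. There were 7 beside 43 true 4-fold and 50 true 16-fold calls in stool at week 1, and 7 beside 47 and 50 in lung. Stool at day 28 had 5 beside 46 and 50, colon 3 beside 47 and 50, and oral swabs 2 beside 41 and 50. These false calls were in part above the 5% that the threshold allows. At the dispersions estimated from the libraries it recovered 0% of 4-fold changes in colon and lung, 2% in oral swabs, 14% in stool at day 28 and 6% in stool at week 1, and 10%, 2%, 26%, 46% and 28% of 16-fold changes, with 0 to 2 false calls in each; with no changed genera it made 0 or 1 false call in each. These simulated libraries were drawn independently around 1 mean per genus. Among the real libraries, other splits called up to 23 genera in colon, 6 in lung and 17 for the difference of the exposure effect between the times. The simulation therefore does not show how many false calls the real libraries give. The permutation test passed 0.05 in 6.0% of 300 rounds with no effect and the PERMANOVA in 3.3% of 60. Fatty acids measured by the study were not analysed here.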

Results

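The study concerns the gut and lung bacteria of mice exposed to nanoplastics. Male mice received nanoparticles of polyethylene terephthalate (PET), the polyester of bottles and textiles, by gavage at 0.5 mg a day in 0.1 ml for 28 days, or were not exposed. Each of 5 sample types, stool after 1 week and stool, colon, lung and oral swab at day 28, gave 6 control and 6 PET libraries, 60 in all. Stool libraries held 16521 to 1083575 counts, colon 59063 to 280575, lung 10543 to 326834 and oral swabs 119454 to 428830. Total counts did not differ between the arms beyond their spread at any site (exact permutation test, lowest adjusted p = 0.495 over 20 library measures). Lung means were 138634 ± 117817 counts in control and 54461 ± 43587 in PET libraries (unadjusted p = 0.139). The p-values below measure the spread between libraries of a group.

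The sites carried different bacteria in the 6 control mice. Stool at day 28 was a mix of unclassified Lachnospiraceae (13.2% ± 4.33, SD, n = 6 here and below), unclassified Muribaculaceae (11.4% ± 2.75) and Bacteroides (9.23% ± 4.08), which are fibre- and glycan-degrading gut anaerobes. Colon tissue was led by Helicobacter, a genus of mucus-dwelling bacteria, at 63.5% ± 34.6 against 5.40% ± 1.80 in stool. Oral swabs were led by Muribacter, a rodent relative of Pasteurella, at 51.3% ± 16.4 and by Streptococcus at 34.02% ± 20.5. Lung had no dominant genus, and its highest mean was Bacteroides at 15.5% ± 17.2. Each pair of sites differed, with R2 from 0.350 for lung and oral swab to 0.528 for stool and oral swab (exact permutation p = 0.0022, the smallest 462 splits can give; adjusted p = 0.0022 over 6 pairs). Kit and site are confounded for stool or oral swab against colon or lung.

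**Figure D1:**
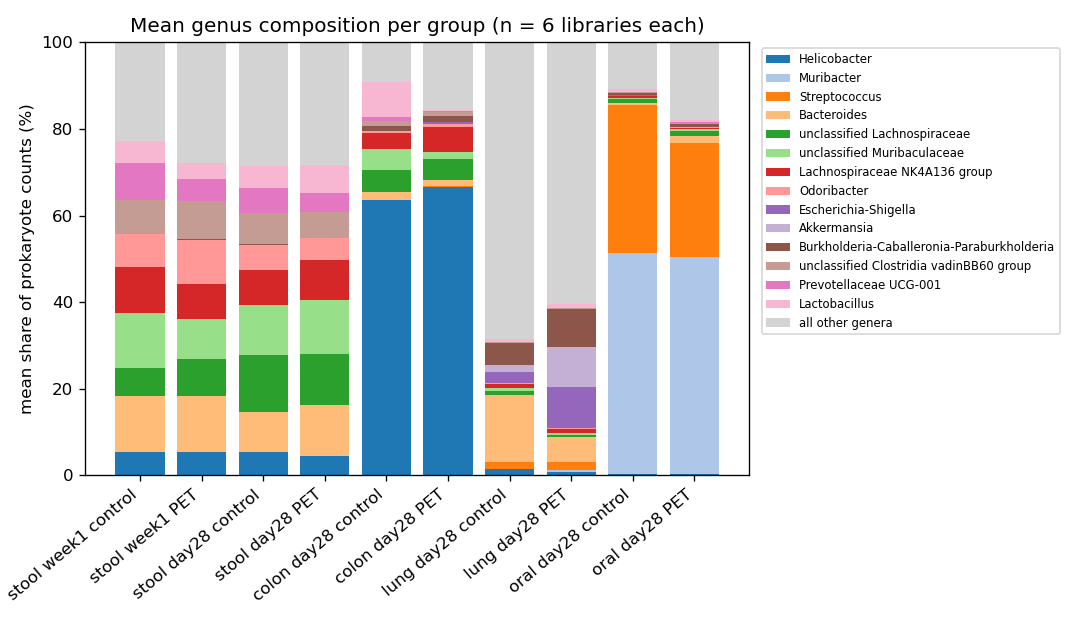
Mean share of prokaryote counts (vertical axis, %) of the most abundant genera in each of the 10 groups (horizontal axis, 6 libraries each); grey is all other genera. Helicobacter fills 63.5% of control and 66.6% of PET colon counts, and Muribacter and Streptococcus fill most of the oral swabs of both arms.

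The colon comparison asked whether 28 days of PET changed the bacteria held in colon tissue. PET colon libraries held 19 genera at higher shares than control, 15 of them with no count in any control library and 8 with all their PET counts in PET libraries 1, 2 and 3. Neisseria was at least 279-fold higher in PET (0.0909% ± 0.106 against 0 counts), Fusobacterium at least 228-fold (0.0741% ± 0.0932), Selenomonas at least 219-fold (0.0737% ± 0.0876) and Cutibacterium, a skin genus, at least 186-fold (0.0747% ± 0.0765). Porphyromonas was at 0.102% ± 0.0797 in PET and 0.000207% ± 0.000507 in control, a ratio of pooled shares of 304 with a 95% exact counting interval of 103.6 to 1478 (699 and 3 counts). Lactobacillus, a lactic acid producer, fell from 8.13% ± 16.1 to 0.257% ± 0.208 (log2 -4.13 ± 1.22, standard error), and Candidatus Arthromitus, the segmented filamentous bacteria of the rodent gut, from 0.817% ± 1.99 to 0.000478% ± 0.000775 (log2 -9.45 ± 2.05). Both calls were lost without control library 2, which held 40.7% Lactobacillus and 4.89% Candidatus Arthromitus.

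edgeR placed 22 colon genera past the threshold, 19 higher and 3 lower in PET, with 27 at an unadjusted p under 0.05. For the 15 genera without control counts, 0 of 976911 counts allows a share of up to 0.000307%. Adjusted p was 0.00293 for Neisseria, Fusobacterium, Selenomonas, Cutibacterium, Porphyromonas, Megasphaera and unclassified F082, 0.0121 for Lactobacillus and 0.00176 for Candidatus Arthromitus. Megasphaera was at least 236-fold higher and unclassified F082, a family of Bacteroidales, at least 295-fold. Next came unclassified Pasteurellaceae (at least 111.8-fold), Corynebacterium (at least 101.3-fold), Leptotrichia (at least 74.8-fold), Gemella (at least 52.2-fold), Catonella and Succinivibrio (each at least 42.6-fold), Capnocytophaga (at least 37.8-fold), Butyricimonas (at least 23.9-fold) and unclassified Lactobacillales (at least 16.96-fold). Dialister (log2 5.57 ± 1.56), Veillonella (4.82 ± 1.64) and unclassified Eubacterium coprostanoligenes group (4.81 ± 1.65) were higher with counts in both arms. Candidatus Stoquefichus was at least 45.5-fold lower in PET. It was detected in 3 of 6 control libraries (0.0128% ± 0.027), with 0.0683% in the highest of them. The bound therefore rests mostly on that library, and it was not computed without it.

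The 19 genera together made up 2.55% ± 3.64 of PET and 0.0445% ± 0.0768 of control colon counts, a sum over genera chosen by the same test; it was 1.09% ± 0.760 without PET library 5 (9.86%) and 0.0134% ± 0.0114 without control library 2 (0.1998%). The 8 genera with 100% of their PET counts in PET libraries 1, 2 and 3 were Neisseria, Selenomonas, Fusobacterium, Leptotrichia, Gemella, Catonella, Capnocytophaga and unclassified F082. Unclassified F082 had 97.6% of its PET counts in PET library 2 and was at least 8.46-fold higher without it. PET library 5 held 93.2% of the PET counts of Megasphaera (at least 17.4-fold higher without it), 79.6% of Succinivibrio (at least 9.40-fold), 94.9% of Dialister and 82.7% of unclassified Eubacterium coprostanoligenes group. Without the PET library highest in each, the other 12 lower bounds lay between 11.8-fold for unclassified Lactobacillales and 163-fold for Neisseria. Porphyromonas was the only one of the 22 whose arms did not overlap; chance gives no overlap to 0.216% of genera. Of the list of rodent oral and airway genera, 5 of 9 tested members rose and none fell (Neisseria, Fusobacterium, Porphyromonas, Veillonella and Gemella), 5 also when adjusted over the list alone. Of the skin and bedding genera, Cutibacterium and Corynebacterium rose, 2 of 3 tested members and 2 adjusted over the list alone. The summed share of neither list passed (adjusted p = 0.159 and 0.476 over all 110 list tests). Streptococcus (log2 1.36, adjusted p = 0.686) and Muribacter (log2 -0.72, adjusted p = 0.908), the main mouse oral genera, did not pass.

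The share of colon counts in features detected in no stool and no oral swab library was 2.26% ± 1.23 in PET and 0.288% ± 0.177 in control, (exact permutation p = 0.0022, a test chosen after the data were seen). The arms parted by a narrow margin, with 0.588% in the lowest PET library and 0.585% in the highest control library. The colon count rested on few libraries. It was 8 without PET library 1, 10 without PET library 2, 10 without PET library 3, 11 without control library 1 and 13 without control library 4. DESeq2 called 10 genera, limma on centred log ratios 1 (Porphyromonas), the stricter filter 2 (Lactobacillus and Candidatus Arthromitus), and the exact permutation test per genus 0, with 24 at an unadjusted p under 0.05.

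Lactobacillus and Candidatus Arthromitus both lost their calls without control library 2, which held 40.7% Lactobacillus (Wilson interval 40.49 to 40.95) and 4.89% Candidatus Arthromitus (4.79 to 4.99). Without it log2 was -2.80 (adjusted p = 0.117) and -4.27 (adjusted p = 0.255). Dialister and unclassified Eubacterium coprostanoligenes group lost theirs without PET library 5 (adjusted p = 0.902 for both), and Dialister also without control library 1 (0.0652). Succinivibrio lost its call in 7 fits, among them the fit without PET library 5 (log2 5.001, adjusted p = 0.0881). Leptotrichia lost its call without control library 1 (log2 9.01, adjusted p = 0.0720; 9.11 with all libraries), and Gemella without control library 1 (8.30, 0.106) or 4 (8.52, 0.0530; 8.40 with all). Corynebacterium, Cutibacterium, Porphyromonas and unclassified Pasteurellaceae kept their calls in 12 of 12 leave-one-out fits. The 10 genera detected in 3 PET libraries fell under the low count filter without any 1 of these, so their calls, Fusobacterium, Megasphaera, Neisseria, Selenomonas and unclassified F082 among them, could not be tested there. Fewer fits kept Butyricimonas (1 of 12), unclassified Lactobacillales (2 of 9), Candidatus Stoquefichus, Capnocytophaga and Catonella (each 4 of 9), Succinivibrio (5 of 12), Veillonella (6 of 12) and unclassified Eubacterium coprostanoligenes group (7 of 12). Over all 12 fits log2 ran from 5.88 to 6.58 for Butyricimonas and 4.42 to 5.11 for Veillonella, so that their fitted change moved little while the adjusted p crossed 0.05. It ran from 5.001 to 8.08 for Succinivibrio and 1.04 to 5.67 for unclassified Eubacterium coprostanoligenes group. Over 9 fits it ran from 6.60 to 7.15 for unclassified Lactobacillales, -7.97 to -7.32 for Candidatus Stoquefichus, 7.67 to 8.22 for Capnocytophaga and 7.71 to 8.26 for Catonella. The genera with 9 fits were each detected in 3 colon libraries, all of 1 arm, and fell under the filter without any 1 of these. Their ranges therefore cannot show how far the change rests on single libraries. Fitted values of genera with no count in 1 arm depend on a prior count. The median log2 change of all colon genera was 0.69 with TMM, and moved by -0.66 with TMMwsp, 0.26 with library totals, -0.33 with DESeq2 and -0.81 with centred log ratios.

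**Figure D2:**
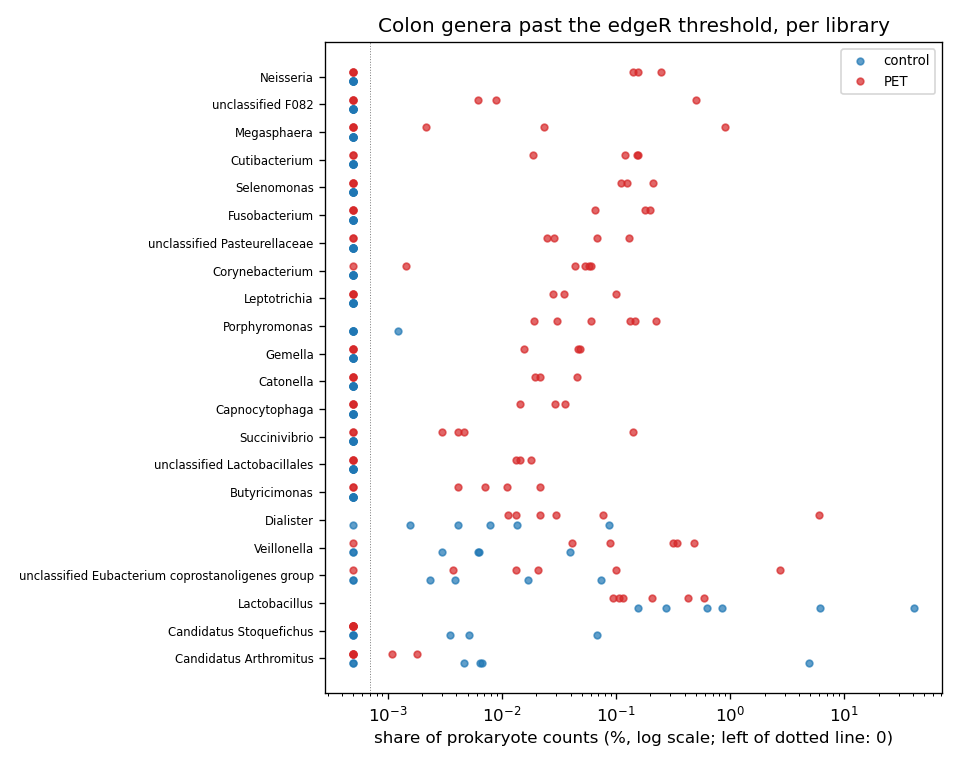
Share of prokaryote counts (horizontal axis, %, log scale) of the 22 colon genera past the edgeR threshold (vertical axis), 1 point per library, control in blue and PET in red, 6 each. Points left of the dotted line are at 0; 15 of the 19 genera higher in PET have all control points there, and Porphyromonas alone has separate arms.

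The most abundant colon genera other than Lactobacillus did not differ past the threshold. Helicobacter was at 63.5% ± 34.6 in control and 66.6% ± 21.9 in PET (log2 -1.21, adjusted p = 0.602); the fitted value has the opposite sign to the difference of the means, and was 0.07 with library totals in place of TMM. Unclassified Lachnospiraceae were at 5.17% ± 5.57 and 4.93% ± 7.66, Lachnospiraceae NK4A136 group at 3.76% ± 4.01 and 5.94% ± 6.29, and unclassified Muribaculaceae at 4.87% ± 4.99 and 1.55% ± 2.88, none past the threshold. Bacteroides (1.75% ± 2.33 and 1.30% ± 0.679), Burkholderia-Caballeronia-Paraburkholderia (1.04% ± 1.27 and 1.36% ± 0.907), unclassified Clostridia vadinBB60 group (1.25% ± 2.44 and 0.842% ± 1.37), Faecalibacterium (0.154% ± 0.246 and 1.27% ± 2.68) and unclassified Clostridia UCG-014 (0.932% ± 1.09 and 0.364% ± 0.655) did not pass either. The arms took an R2 of 0.0854 of the community distances (exact permutation p = 0.476, adjusted p = 0.739). Shannon index was 2.24 ± 1.29 in control and 2.50 ± 1.02 in PET (exact adjusted p = 0.820), and richness 282 ± 135.6 and 365 ± 125.1 features (exact adjusted p = 0.741). The control means hide 2 sets of libraries. Control libraries 1, 2 and 3 had Shannon values of 3.30 to 3.50 and 397 to 408 features. Control libraries 4, 5 and 6 had values of 0.840 to 1.36 and 120 to 212 features. Helicobacter ran from 12.4% in control library 2 to 96.4% in control library 4. The Shannon difference of 0.26 lay between -0.02 and 0.51 as single libraries were left out.

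Stool after 1 week tested for an early effect of PET. Alistipes, a bile-tolerant gut anaerobe, was at 4.25% ± 1.19 in control and 6.68% ± 1.52 in PET stool, and Odoribacter, a butyrate producer, at 7.60% ± 2.59 and 10.2% ± 3.09. Prevotellaceae UCG-001 was at 8.43% ± 0.934 and 5.09% ± 2.92, unclassified Muribaculaceae at 12.6% ± 4.201 and 9.30% ± 3.39, and Lachnospiraceae NK4A136 group at 10.6% ± 3.33 and 7.97% ± 3.69. Bacteroides was at 12.9% ± 4.79 and 12.9% ± 3.84, unclassified Clostridia vadinBB60 group at 7.90% ± 2.43 and 8.74% ± 1.78, unclassified Lachnospiraceae at 6.68% ± 2.43 and 8.54% ± 2.25, Helicobacter at 5.33% ± 2.28 and 5.47% ± 2.01, and Lactobacillus at 5.21% ± 3.50 and 3.69% ± 1.37. None of these differences passed the test, with adjusted p of 0.310 for unclassified Muribaculaceae and Lachnospiraceae NK4A136 group and 0.370 for Prevotellaceae UCG-001.

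At week 1 edgeR called 0 stool genera, with 14 at an unadjusted p under 0.05. DESeq2 and limma also called 0, as did the exact permutation test per genus, which can rarely pass adjustment with so few libraries. The median log2 change of all genera was 0.09 with TMM and moved by 0.37 with TMMwsp and 0.49 with library totals. The arms took an R2 of 0.115 (exact permutation p = 0.165, adjusted p = 0.739). Shannon index was 4.44 ± 0.197 and 4.56 ± 0.266 (exact adjusted p = 0.819), and richness 360 ± 96.9 and 502 ± 240 features (exact adjusted p = 0.741). The richness difference of 142.02 features ranged from 45.4 to 196 as single libraries were left out. Control library 1 held 16521 counts, and all stool of that week was compared at 16513 prokaryote counts.

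Stool at day 28 tested for the effect of the whole exposure. Unclassified Lachnospiraceae were at 13.2% ± 4.33 in control and 11.9% ± 5.24 in PET, unclassified Muribaculaceae at 11.4% ± 2.75 and 12.4% ± 4.46, and Bacteroides at 9.23% ± 4.08 and 11.6% ± 2.83. Lactobacillus was at 4.87% ± 1.67 and 6.46% ± 2.68, and Helicobacter at 5.40% ± 1.80 and 4.47% ± 1.67. Lachnospiraceae NK4A136 group (8.18% ± 2.70 and 9.41% ± 3.16), unclassified Clostridia vadinBB60 group (7.28% ± 2.87 and 5.99% ± 2.32), Alistipes (5.89% ± 2.23 and 6.66% ± 2.00), Odoribacter (5.76% ± 3.17 and 4.98% ± 2.42) and Prevotellaceae UCG-001 (5.77% ± 2.22 and 4.56% ± 2.40) complete the 10 most abundant. Among these 10 genera the lowest adjusted p was 0.814.

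At day 28 edgeR called 0 stool genera, with 9 at an unadjusted p under 0.05. DESeq2 and limma also called 0, as did the exact permutation test per genus, which can rarely pass adjustment. The median log2 change of all genera was -0.11 with TMM and moved by -0.16 with TMMwsp, 0.16 with DESeq2 and 0.18 with centred log ratios. The arms took an R2 of 0.0712 (exact permutation p = 0.814, adjusted p = 0.814). Shannon index was 4.74 ± 0.110 and 4.74 ± 0.112 (exact adjusted p = 0.978), and richness 565 ± 151 and 550 ± 56.4 features (exact adjusted p = 0.935). Without control library 1, which had 871 features, the richness difference went from -14.9 to 46.2 features.

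The change of stool from week 1 to day 28 was asked of each arm. Muribacter, the main oral genus, had 0 counts in all 12 week 1 stool libraries and was detected at day 28 in 4 of 6 control (0.0238% ± 0.0194) and 5 of 6 PET libraries (0.0195% ± 0.0106), with edgeR adjusted p of 0.141 and 0.0721. Agathobacter, a butyrate producer, was detected in all 6 PET stool libraries at week 1 (0.00931% ± 0.00706) and in 0 at day 28 (adjusted p = 0.0787). Izhakiella went from 0.0417% ± 0.0670 to 0.000189% ± 0.000464 in control stool (adjusted p = 0.155). These genera were chosen after their values were seen.

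edgeR called 0 of 144 genera over time in control stool, with 25 at an unadjusted p under 0.05, while DESeq2 called 4 and limma 0. The DESeq2 calls were Chlamydia and Izhakiella, lower at day 28, and Muribacter and Eisenbergiella, higher. Eisenbergiella was detected in 1 of 6 day 28 control libraries, at 0.0112%, and its DESeq2 log2 of 20.3 rests on that library. For Chlamydia the edgeR direction rested on week 1 control library 5, without which the edgeR log2 went from -5.66 to 0.40 (edgeR adjusted p = 0.205 and 0.946). On log2 shares week 1 stayed higher by 1.28 without that library (exact permutation p = 0.602). In PET stool edgeR called 0, with 42 at an unadjusted p under 0.05, while DESeq2 called 10 (2 higher and 8 lower at day 28) and limma 13 (3 higher and 10 lower). Both tools called 8 genera in the same direction, Muribacter and Streptococcus higher and Agathobacter, Akkermansia, Bifidobacterium, Romboutsia, Subdoligranulum and UCG-002 lower. DESeq2 also had Dialister and Escherichia-Shigella lower. limma also had unclassified Christensenellaceae higher and Catenibacterium, Christensenellaceae R-7 group, Eubacterium hallii group and Prevotella lower. Without stool day 28 control library 1 edgeR called 5 genera over time in control and 7 in PET stool, Muribacter, Agathobacter and UCG-002 in both, with Catenibacterium and Prevotella the others in control and Christensenellaceae R-7 group, Dialister, Eubacterium hallii group and Subdoligranulum in PET; all but Muribacter were lower at day 28. Genera named here from other tools or fits were chosen after their values were seen. Muribacter was the 1 genus called over time in PET stool without day 28 control library 6 or day 28 PET library 6. For the difference of the exposure effect between the times edgeR called 0, with 34 at an unadjusted p under 0.05, DESeq2 1 (Eisenbergiella, with counts in 1 day 28 control library) and limma 0. The median log2 changes of all genera were 0.30, -0.10 and -0.38 in these contrasts with TMM, and -0.26, 0.18 and 0.42 away from that with DESeq2.

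The lung comparison asked whether PET given by mouth goes with a change of lung bacteria. Bacteroides was at 15.5% ± 17.2 in control and 5.66% ± 5.55 in PET lung, Escherichia-Shigella at 2.54% ± 3.89 and 9.46% ± 16.5, and Akkermansia, a mucin degrader, at 1.64% ± 3.49 and 9.23% ± 21.3. Burkholderia-Caballeronia-Paraburkholderia was at 5.16% ± 6.62 and 8.88% ± 6.94, Faecalibacterium, a butyrate producer, at 4.21% ± 3.03 and 1.76% ± 1.12, and Prevotella at 5.01% ± 5.35 and 4.003% ± 4.38. UCG-002 (4.10% ± 5.55 and 1.91% ± 3.35), Blautia (1.99% ± 1.17 and 2.84% ± 3.80), Veillonella (1.67% ± 2.93 and 2.66% ± 2.72) and Subdoligranulum (2.85% ± 3.43 and 1.43% ± 0.665) follow. None of the 10 passed, with a lowest adjusted p of 0.568 for Faecalibacterium.

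Both lung libraries with later numbers, 5 and 6, were control, so a difference of run, if there was one, would fall on 1 arm. Control library 6 also had 33.96% of its counts without a taxonomy line, the highest of the lung libraries. edgeR called 0 of 232 lung genera, with 20 at an unadjusted p under 0.05. DESeq2 called 4, all higher in PET: Duganella, Lactococcus, Pseudomonas and Serratia. limma called 0, and edgeR with no low count filter called Coprobacillus, lower in PET. The exact permutation test per genus, which can rarely pass adjustment, called 0. Pseudomonas was at 0.0393% ± 0.0398 in control and 0.575% ± 0.374 in PET (edgeR log2 3.65 ± 1.54, adjusted p = 0.363); the edgeR median of all lung genera moved by -0.21 with TMMwsp. The arms took an R2 of 0.0859 (exact permutation p = 0.591, adjusted p = 0.739), Shannon index was 4.80 ± 0.782 and 4.38 ± 1.24 (exact adjusted p = 0.819), and richness 480 ± 211 and 420 ± 241 features (exact adjusted p = 0.755). The richness difference of -60.1 features ranged from -157 to 16.1 as single libraries were left out, and the Shannon difference of -0.42 from -0.76 to -0.08.

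Features also detected in gut samples held 53.9% ± 13.2 of control and 61.3% ± 17.7 of PET lung counts (exact permutation p = 0.448), and features of oral swabs 56.9% ± 13.9 and 63.2% ± 18.3 (exact permutation p = 0.509). Most of these counts lay in features of both sets: those of the gut alone held 5.02% ± 3.73 and 2.64% ± 1.31, and those of the mouth alone 7.99% ± 6.06 and 4.48% ± 3.41, so that with these sets the difference turned. Features in neither set held 38.1% ± 14.7 and 34.2% ± 18.6.

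The oral swab comparison asked the same of the mouth. Muribacter was at 51.3% ± 16.4 in control and 50.1% ± 12.5 in PET swabs, Streptococcus at 34.02% ± 20.5 and 26.5% ± 16.7, and Rodentibacter, a rodent airway genus, at 1.75% ± 1.19 and 4.56% ± 8.78. Campylobacter was at 0.126% ± 0.159 and 1.23% ± 1.82 (log2 2.33, adjusted p = 0.786), and Bacteroides at 0.498% ± 0.335 and 1.61% ± 2.66 (adjusted p = 0.786). Unclassified Lactobacillales (1.501% ± 1.15 and 1.28% ± 0.623), unclassified Lachnospiraceae (0.843% ± 0.483 and 1.09% ± 1.15), Bergeyella (1.36% ± 1.54 and 0.569% ± 0.153), Porphyromonas (1.29% ± 2.30 and 0.587% ± 1.41) and Lactobacillus (0.599% ± 0.9998 and 0.543% ± 0.809) did not pass. edgeR called 0 of 175 genera, with 7 at an unadjusted p under 0.05, and DESeq2 and limma called 0. The exact permutation test per genus, which can rarely pass adjustment, also called 0. The median log2 change of all genera was 0.14 with TMM and moved by 0.42 with library totals and -0.22 with TMMwsp. The arms took an R2 of 0.0915 (exact permutation p = 0.374, adjusted p = 0.739), which was 0.0693 to 0.160 as single libraries were left out. Shannon index was 2.18 ± 0.305 and 2.46 ± 0.871 (exact adjusted p = 0.819), and richness 401 ± 104.05 and 358 ± 170 features (exact adjusted p = 0.755). As single libraries were left out the Shannon difference of 0.28 ranged from 0.01 to 0.45, and the richness difference of -43.0 features from -103 to -7.43.

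**Figure D3:**
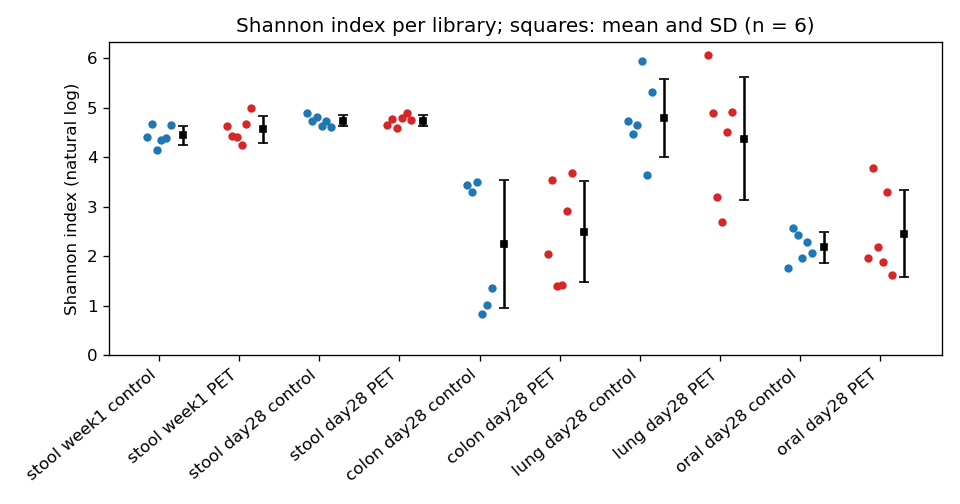
Shannon index (vertical axis, natural log) of each library (points, control in blue, PET in red) in the 10 groups (horizontal axis), with mean and SD as black squares and bars (n = 6). Stool means lie between 4.44 and 4.74, oral swab means at 2.18 and 2.46, and no arms differ past the threshold.

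The taxon lists summed small changes over related bacteria. None of the 110 list tests passed (lowest adjusted p = 0.159), 8 were at an unadjusted exact permutation p under 0.05, and 0 passed with a pseudocount of 5 or with percent shares. In 22 tests the log2 and percent differences had different signs. In the colon, rodent oral and airway genera held 0.103% ± 0.0587 of control and 0.810% ± 0.595 of PET counts (exact p = 0.00433), and skin and bedding genera 0.00112% ± 0.00273 and 0.144% ± 0.138 (exact p = 0.0173). Colon enterobacteria went from 0.0498% ± 0.0793 to 0.677% ± 1.38 (exact p = 0.0238; 0 of 1 tested member past the threshold and 0 adjusted over the list alone), and to 0.114% ± 0.0806 without PET library 5 (exact p = 0.0519). With families in place of genera edgeR called Enterobacteriaceae higher in PET colon (log2 3.17 ± 1.16, adjusted p = 0.0462). Colon lactic acid bacteria and bifidobacteria went from 8.21% ± 16.2 to 0.403% ± 0.199 (exact p = 0.147, where 1 of 3 fell, Lactobacillus, and 1 adjusted over the list alone), and colon Verrucomicrobiota from 0.310% ± 0.415 to 0.967% ± 0.853 (exact p = 0.0736). Control library 2 held 40.7% Lactobacillus and carried most of the control mean of the lactic acid list.

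In week 1 stool, common reagent contaminants went from 0.00973% ± 0.00500 to 0.138% ± 0.288 (exact p = 0.00216; 0 of 2 members past the threshold, 2 adjusted over the list alone, Burkholderia-Caballeronia-Paraburkholderia and Sphingomonas). Without PET library 6, which held 0.725%, the PET mean was 0.0200% ± 0.00438 (exact p = 0.00433), and with a pseudocount of 5 the log2 went from 1.95 to 1.36 (exact p = 0.0498). Week 1 Actinobacteriota went from 0.115% ± 0.0458 to 0.202% ± 0.0701 (exact p = 0.0260; 0 of 7 past the threshold, 1 adjusted over the list alone) and Desulfobacterota from 1.101% ± 0.532 to 0.485% ± 0.528 (exact p = 0.0346). Week 1 sulfate and sulfite reducers (0.0448% and 0.0789%, exact p = 0.117), Oscillospiraceae with Ruminococcaceae (3.25% and 4.27%, exact p = 0.104) and Muribaculaceae (12.8% and 9.45%, exact p = 0.149; 1 of 2 fell adjusted over the list alone, none over all genera) were less apart. In day 28 stool, Erysipelotrichaceae went from 0.127% ± 0.176 to 0.0247% ± 0.0169 (exact p = 0.0303, with 0 of 1 past the threshold and 1 adjusted over the list alone) and mucus-associated genera from 5.68% to 4.94% (exact p = 0.465). Most of the Erysipelotrichaceae control mean came from 1 library, with 0.474% unclassified Erysipelotrichaceae.

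In the lung, genera with described PET hydrolases, here Pseudomonas and Bacillus, went from 0.109% ± 0.149 to 0.633% ± 0.350 (exact p = 0.00433, with 0 of 2 past the threshold and 0 adjusted over the list alone). Pseudomonas, at the lung shares given above, held most of the PET sum. It is also on the list of common reagent contaminants. Lung Bacteroidota went from 28.98% ± 18.1 to 14.7% ± 7.47 (exact p = 0.0693), acetate and propionate producing Bacteroidota from 26.1% to 12.5% (exact p = 0.0628) and Proteobacteria from 14.1% ± 10.02 to 26.1% ± 15.7 (exact p = 0.134). Lung butyrate producers (14.2% and 8.92%, exact p = 0.338), Firmicutes (45.2% and 37.7%, exact p = 0.331), Lachnospiraceae (12.6% and 11.4%, exact p = 0.405) and gut anaerobe families (31.7% and 20.8%, exact p = 0.271) were within the spread, as were oral Campylobacterota (0.295% and 1.499%, exact p = 0.342). Each of these values is from the comparison in which its list had its lowest p. The 2 list values without a PET library, and the colon sum and lower bounds without 1 library, were chosen after the data were seen.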

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

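The tests of depth, neighbouring positions, foreign DNA, mouth (in colon and lung), gut and reagent bacteria, and the counts of other splits of the libraries, were chosen after the colon calls and lung shares they bear on were seen; for depth, neighbouring positions, foreign DNA and reagent DNA the bounds were set before the test's own value was computed. In 146 groups of 6 libraries, 36 had 1 library far from the other 5, its gap to the nearest library being above 0.625 of the whole range of the group. For normally distributed values chance gives this in about 1 in 20 groups, or 7.3 of 146. Shares of genera need not be distributed so, and 36 against 7.3 therefore does not show an excess. The values below are each such library. Wilson 95% intervals of the single shares reach at most 0.605 percentage points to a side.

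In stool, week 1 control library 1 was low in total count at 16521, week 1 PET library 6 was high in richness at 985 features and day 28 control library 1 at 871 features. Lachnospiraceae NK4A136 group was high at 14.98% in week 1 PET library 5 and 13.3% in day 28 control library 5, and Alistipes at 10.2% in day 28 control library 3. In the colon, PET library 6 had the highest total count, 280575, and 7.38% unclassified Muribaculaceae. PET library 2 held 20.04% unclassified Lachnospiraceae and 3.57% unclassified Clostridia vadinBB60 group. Colon control library 2 held 40.7% Lactobacillus, 6.17% unclassified Clostridia vadinBB60 group, 3.56% Burkholderia-Caballeronia-Paraburkholderia and 0.654% Faecalibacterium, and control library 1 held 6.30% Bacteroides. Colon PET library 5 held 6.72% Faecalibacterium and 1.69% unclassified Clostridia UCG-014.

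In the lung, PET library 1 was high in richness at 904 features. Akkermansia was at 52.7% in lung PET library 4 and 8.74% in control library 4, and Escherichia-Shigella at 42.9% in PET library 3 and 10.4% in control library 1. Burkholderia-Caballeronia-Paraburkholderia was at 18.1% in control library 3, Faecalibacterium at 10.04% in control library 2, Veillonella at 7.63% in control library 4, UCG-002 at 8.71% in PET library 2 and Blautia at 10.1% in PET library 6. Subdoligranulum was low at 0.116% in PET library 4. In oral swabs, PET library 5 held 22.4% Rodentibacter, 2.17% Lactobacillus and 4.18% of counts without a taxonomy line. Porphyromonas was at 5.66% in control library 4 and 3.47% in PET library 6, Bacteroides at 6.93% in PET library 2, and control library 2 held 2.63% Lactobacillus and 1.77% unclassified Lachnospiraceae.

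The 19 genera higher in PET colon, among them Neisseria, Fusobacterium, Selenomonas, Cutibacterium and Porphyromonas, could reflect exposure, depth, bulk transfer from the mice's own mouths, foreign DNA or carry-over between wells. Greater depth of the PET libraries as the whole cause is argued against: PET colon libraries had fewer total counts (129461 ± 79267) than control (166474 ± 43929) on average. With every colon library thinned to 55824 counts, 16 of the 19 were still called higher, but thinning could only keep the 0 control counts of 15 of them. Thinning cannot test whether libraries with fewer counts held a larger share of foreign DNA. Bulk transfer from the mouth as the whole cause is argued against too: Muribacter and Streptococcus had at most 0.654 times the counts of these genera in a PET colon library, and at least 3.27 times in an oral swab library. The bound for this test was set after the data were seen. These genera were also chosen for being high in PET colon, which lowers the ratio there. It was lowest, 0.0362, in PET library 5. Foreign DNA stays open: 35.95% of the PET counts of these genera lay in features of no stool or oral swab library, between the bounds of 10% and 50% set before this value was computed, while 62.4% lay in features of at least 1 lung library and 26.3% in features of no stool, oral swab or lung library. These shares are pooled over counts. PET library 5 weighs heavily in them, with 9.86% of its counts in these genera against 0.160 to 1.85% in the other PET colon libraries. They may therefore not hold for the genera of PET libraries 1, 2 and 3. Carry-over stays open too: 22.8% of a PET colon library's counts of these genera lay on average in features of the lung library at the neighbouring position against 27.8% over all 36 pairs, which met the bound set against carry-over but lay within the spread of the 720 pairings (one-sided exact p = 0.801), and the demand that it exceed that spread was added after the value was seen. If the letters and numbers in the library names are plate positions, all 6 PET colon libraries had number 3 and all 6 control colon libraries number 2, so that position and exposure cannot be told apart, and an effect of PET stays among the open explanations as untested.

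The lung libraries, with Bacteroides, Burkholderia-Caballeronia-Paraburkholderia, Escherichia-Shigella and Akkermansia at the top, could carry bacteria from the mouth, from the gut or DNA from reagents. Bulk transfer from the mouth is argued against: the 3 features that hold 51.0% of oral swab counts held on average 0.479% of lung counts, at most 1.57% in a library. The gut stays open: the 13 features that hold 50.4% of stool and colon counts held 1.38% of lung counts, with 5.63% in the highest library. Reagent DNA stays open: the share of reagent contaminant genera and log10 depth had Spearman's rho -0.39 (permutation p = 0.210) and Pearson's r -0.50 (permutation p = 0.102) over 12 libraries, and r was -0.63 (permutation p = 0.0584) without the 2 libraries farthest from the median depth. Within the arms rho was -0.37 in control and 0.03 in PET, with 6 libraries each (exact permutation p = 0.497 and 1).

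The 22 colon genera were set against other splits of the 12 colon libraries. Of 100 splits drawn from 462, 3 called as many genera, the real one included, and the highest other called 23. That share lay under the bound of 0.05 among the splits drawn. The 2 others of 99 give a 95% exact interval of 0.246 to 7.11% for the share of all splits. This interval reaches above 0.05, so chance was not excluded. The other comparisons had 0 genera called in the real groups, which 100 of 100 splits match whatever the data, so for these the count of splits says nothing about chance. The highest other split called 1 genus in stool at week 1, 1 in stool at day 28, 6 in lung, 1 in oral swabs, 2 over time in control stool, 1 over time in PET stool and 17 for the difference of the exposure effect between the times. Whether a structure of the libraries other than the exposure lies behind the 17, or the 6 in lung, was not tested.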

How the results depend on the processing

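For the colon, limiting features to those seen in stool or oral swabs and thinning the counts were chosen after the data were seen; all other alternatives given here were planned. Over the results that answer a comparison, 497 values kept their direction and side of the threshold, 24 counts moved by over 1.5 times and 12 differences turned sign; the cause was not tested unless named. Of the values of the 22 called colon genera, 302 kept the call, 140 lost it and 0 turned; 650 shares of abundant genera moved by under 1 SD. Colon genera called went from 22 to 10 with DESeq2, 1 with limma on centred log ratios (Porphyromonas), 2 with the stricter filter (47 genera tested; Lactobacillus and Candidatus Arthromitus), 11 with features in place of genera (5 higher, 6 lower), 0 with the exact permutation test per genus (24 at an unadjusted p under 0.05) and 4 with features also seen in stool or oral swabs (Cutibacterium and unclassified F082 higher, Lactobacillus and Candidatus Arthromitus lower). The other colon settings gave 17 to 23. Lung went from 0 to 4 with DESeq2 and 1 without a low count filter (Coprobacillus). Time in control stool went from 0 to 4 with DESeq2 and 1 without the later numbered libraries (Muribacter). Time in PET stool went to 10 with DESeq2, 13 with limma and 1 without the later numbered libraries (Muribacter). The difference between the times went to 1 with DESeq2 (Eisenbergiella) and 3 with families (Burkholderiaceae, Coriobacteriaceae and Microbacteriaceae). The Shannon difference of day 28 stool turned from 0.00200 to -0.0491 with genera and -0.0250 without the later numbered libraries. Lung counts in gut features turned from 7.43 to -2.38 percentage points, and in oral features from 6.30 to -3.50, with features of the reference site only. Leaving out 1 library at a time gave 8 to 22 colon genera (8 without PET library 1), 0 to 5 over time in control stool and 0 to 7 in PET stool (5 and 7 without day 28 control library 1). It gave a Shannon difference of -0.0293 to 0.0343 and a richness difference of -32.9 to 46.2 features in day 28 stool, a Shannon difference of -0.0221 to 0.510 in colon and a richness difference of -157 to 16.1 features in lung. No library was under 1000 counts, so that alternative was not run. No paired analysis was possible because no label ties libraries of 1 animal together. Depth limits the lung most: a library of 10543 counts, 10083 of them prokaryote, allows a genus with 0 counts a share of up to 0.0298%.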

Other observations

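All values and tests of this part were chosen after the data were seen. Chlamydia, a genus of intracellular bacteria with a species that lives in the mouse gut, was present in all 12 week 1 stool libraries at a mean of 1.47% ± 3.52 (SD, n = 6) in control and 1.30% ± 2.48 in PET. Its highest shares were 8.65% in control library 5 (Wilson interval 8.56 to 8.74) and 6.32% in PET library 3 (6.23 to 6.41). Without these libraries the week 1 means were 0.0294% ± 0.0236 in control, below the day 28 mean, and 0.295% ± 0.402 in PET. At day 28 it was at 0.0438% ± 0.0441 in control and 0.0566% ± 0.0575 in PET stool (exact permutation p = 0.297 and 0.0152, adjusted p = 0.297 and 0.0303 over 8 tests of 4 genera in 2 arms). Colon tissue at day 28 held Chlamydia at 0.282% ± 0.422 in 4 of 6 control libraries and 0.783% ± 0.915 in all 6 PET libraries. Muribacter, at 0 in week 1 stool, gave an exact permutation p of 0.0411 in control and 0.00433 in PET stool over time (adjusted p = 0.0658 and 0.0173), Agathobacter 0.0758 and 0.00216 (0.101 and 0.0173) and Izhakiella 0.00649 and 0.173 (0.0173 and 0.198). These 4 genera were picked for their change, so the p-values are not independent of it.

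The segmented filamentous bacteria that were lower in PET colon were present in stool of both arms. Candidatus Arthromitus was at 0.0694% ± 0.119 in 4 of 6 control and 0.0484% ± 0.0720 in 3 of 6 PET stool libraries at day 28. Candidatus Stoquefichus was detected in all 6 control (0.0362% ± 0.0324) and 4 of 6 PET stool libraries (0.00790% ± 0.00979). Neither passed the test in stool (edgeR adjusted p = 0.972 and 0.814).

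A few genera had arms that did not overlap without passing the edgeR threshold; chance gives no overlap to 0.216% of genera, or 0.502 of the 232 in lung. In lung these were Pseudomonas and unclassified Enterobacteriaceae, the latter at 0.0270% ± 0.0304 in control and 0.295% ± 0.126 in PET (edgeR adjusted p = 0.628). In week 1 stool it was Burkholderia-Caballeronia-Paraburkholderia, at 0.00834% ± 0.00438 and 0.116% ± 0.245 (edgeR adjusted p = 0.323), with a PET mean of 0.0157% ± 0.00241 without PET library 6, which held 0.616%. In oral swabs it was Desulfovibrio, at 0.0107% ± 0.00320 and 0.00362% ± 0.00272 (edgeR adjusted p = 0.786), and in day 28 stool no genus did so.

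The exposure effect on stool diversity was compared between the times by exact permutation of the arms within each time. The difference of Shannon index between PET and control was 0.12 at week 1 and 0.00 at day 28 (permutation p = 0.435), and that of richness 142.02 and -14.9 features (permutation p = 0.259). Week 1 values were computed at 16513 prokaryote counts and day 28 values at 245010. The richness differences are therefore not on one scale, so their test cannot tell whether the exposure effect on richness changed.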
